A study of Mus musculus with 18 samples.

How the data were processed

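Total RNA from extraocular, leg and heart muscle of mdx and dko mice was measured on 18 Affymetrix mouse expression arrays, 3 in each of 6 groups of tissue and genotype. The values are intensity on a linear scale, and each array had been scaled by the authors, before the table was deposited, to about the same mean with 2% trimmed from each tail (1500.69 to 1501.15); this was read from the values. The software is not given in the sources used here, nor are detection calls, scan dates or the animal each sample came from. All 18 columns of the table belonged to these arrays and 0 to other series. The depth of the arrays is given by their medians and maxima, and their number limits the precision.

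The table held 12488 probe sets. The 66 hybridization and labelling controls were left out of the tests and checked apart: 0 of them changed between dko and mdx in any tissue (smallest adjusted p 0.202, in leg with the replicate block). Gene symbols came from the supplied probe table; of the other 12422 probe sets, 10833 had 1 symbol, 396 had several and 1193 had none, and 0 symbols changed when they were looked up by gene ID. Only probe sets with 1 symbol were given a gene's name. Those above the 40th percentile of an array in at least 3 of the 18 arrays were tested, which left 8888 probe sets, 7977 of them with 1 symbol, for 6551 genes. Values were used as deposited, since the trimmed means lay within 10% of each other. An offset of 166.7, the median of the arrays' 25th percentiles, was added before the base-2 logarithm was taken, so that a fold change of a dim probe set is smaller than the ratio of its means.

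Group means for the 6 groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend or robust options; 12 residual and 3.52 prior degrees of freedom). The p-values were adjusted by the method of Benjamini and Hochberg over all 8888 probe sets within a contrast, and an adjusted p under 0.05 was called; the tests were two-sided. The contrasts were dko against mdx in each tissue, the 3 differences between those changes, and mdx extraocular muscle and mdx heart each against mdx leg. Utrn and Dmd were also tested by exact permutation of the genotypes within each tissue, over 8000 assignments, on the mean log2 difference of the 3 tissues; this permutation was two-sided. It was repeated with genotypes exchanged only within the 9 pairs of the same tissue and number, over 512 assignments, a test chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

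Replicate numbers were checked for pairing, because the labels number the samples of each group from 1 to 3 without saying what the numbers mean. The correlation of deviations from group means, taken across genes, was 0.404 to 0.751 between dko and mdx arrays of the same number and tissue (9 pairs). Between arrays of the same number in other tissues it was 0.327 to 0.74 (36 pairs), with a median of 0.538 for the same genotype and 0.535 for the other genotype. Between number 3 and number 1 or 2 it was -0.628 to -0.28, and between numbers 1 and 2 it was 0.0343 to 0.311. The first component of the deviations held 56.4% of their variance. The number therefore marks something the arrays share across tissues and genotypes, and it does not show that tissues came from the same animal. Comparisons of dko and mdx, and the differences between them, were repeated with the replicate number within tissue as a block (6 residual and 3.79 prior degrees of freedom). Comparisons between mdx tissues were repeated with a block common to all arrays (10 residual and 4.04 prior degrees of freedom).

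There were 36 gene lists. Their purpose was to show which tissue programmes and which cell types moved. Muscle programmes were covered by the dystrophin-associated complex and costamere, neuromuscular junction, regeneration and embryonic muscle, fast and slow contractile proteins, calcium handling, cardiac muscle, cardiac stress response, and regional patterning of limb and trunk and of the head. Markers of other cells were covered by macrophage, T cell, B cell, erythroid, adipocyte, nerve and Schwann cell, lacrimal and Harderian gland, retina and eye pigment, endothelium, smooth muscle, skin and mucosal epithelium, tendon and cartilage, and lung. General programmes were cell division, extracellular matrix and fibrosis, chemokine, cytokine and complement, antigen presentation and interferon response, glycolysis and glycogen, oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation, glucocorticoid and fasting response, ubiquitin, proteasome and lysosome, heat shock and oxidative stress, immediate early genes, and ribosomal protein. Each gene was represented by its probe set with the highest mean. Lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the 36 lists within a contrast, and again with an estimated correlation. Members were counted past the threshold over all probe sets and adjusted over the list alone. All lists had the 3 members needed, and 0 were left untested.

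Genes were named by a rule: Utrn and Dmd in each comparison of dko with mdx; the 8 largest rises and the 8 largest falls among called probe sets with 1 symbol whose 3 arrays did not overlap the other group's 3; up to 3 called members of each list; and, where fewer than 5 probe sets were called, the 5 with the smallest unadjusted p. Genes named outside the rule, such as Ucp1, Ms4a6c, Col5a2, Bgn, C1qc, Tpm3, Tnni1 and the members counted over a list alone, were chosen after their values were seen.

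The group labels, contrasts, tests, filter, offset, lists, naming rule and a first set of other settings were fixed before the data were examined. That first set was quantile normalization, scaling to a common 75th percentile, an offset lowered to 41.68 or raised to 666.8, no filter, a filter at the 60th percentile, the trend and robust options, a fit of only the arrays compared, the replicate number within tissue as a block, a random block in which arrays of 1 genotype and number were taken as 1 animal across tissues (duplicateCorrelation, consensus correlation 0.526), leaving out each array in turn, and an estimated correlation in camera. Chosen after seeing the data were the block common to all arrays, a fit of numbers 1 and 2 only, and the block together with each other setting, including the estimated correlation in camera. Lists under the trend and random-block fits were tested with cameraPR.

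The steps were tested on simulated data, with 8888 probe sets and 3 arrays per group, in which known changes in dko leg were put on 50 (1.5-fold), 100 (2-fold) and 50 (4-fold) of the probe sets. Without the block 0% of 1.5-fold, 13% of 2-fold and 70% of 4-fold changes were recovered, with 0 false calls; with it 22%, 60% and 92% were recovered, with 4 false calls. A raised list of 30 genes gave a camera p of 1.16e-46 and an unchanged list 0.462. The noise was drawn independently for each gene, so this does not test the lists where genes vary together. The simulated arrays also carried shifts of each replicate number and the spread left after the block. The better recovery with the block was therefore built in. Probe-level files were not available, so background, saturation and detection could not be examined below the level of the probe set.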

Results

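Total RNA from extraocular muscle (the muscles that move the eye), leg muscle and heart was measured on 18 mouse expression arrays. Each tissue was taken at 8 weeks of age from mdx mice, which lack dystrophin and are the controls by the labels, and from dko mice, with 3 arrays in each of the 6 groups. By usual usage dko stands for mice that lack both dystrophin and its relative utrophin. The labels do not spell the term out. The labels do not say whether the replicates are separate animals, so the p-values measure only the spread between these samples, which may be technical. Array medians ran from 525.6 to 671.8 intensity units and array maxima from 33355 to 74434.

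The arrays numbered 3 stood apart in all 6 groups. Their medians were 525.6 to 573.75, against 612.6 to 671.8 on the arrays numbered 1 or 2, and their maxima were 47024 to 74434, against 33355 to 47589. Dko and mdx arrays of the same number and tissue deviated from their group means alike, with a median correlation of 0.61 over 9 pairs, taken across genes, which are not independent replicates. For that reason each count is given first without and then with the replicate number as a block. Values below are mean intensity ± SD (n = 3), and fold changes were taken from the logarithm after the offset was added.

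**Figure D1:**
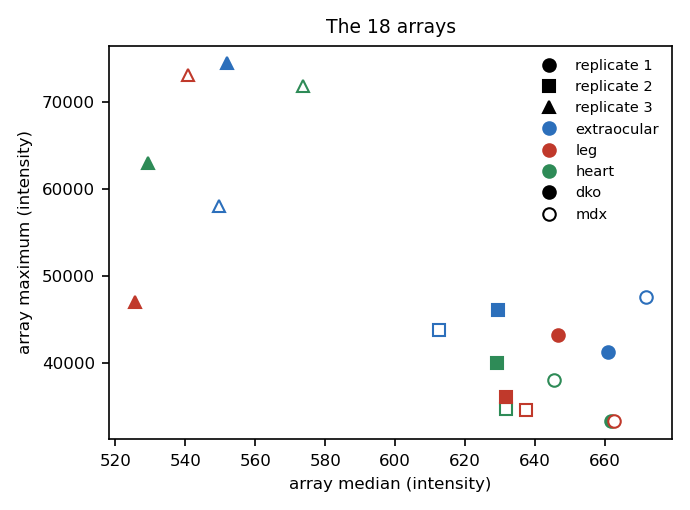
Median (horizontal axis, intensity) against maximum (vertical axis, intensity) of each of the 18 arrays, with shapes for replicate number, colours for tissue and filled symbols for dko. The arrays numbered 3 have medians of at most 573.75, below the lowest median of the others, 612.6.

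The first question was whether the gene that separates dko from mdx was lower in dko. Utrn encodes utrophin, which links the muscle membrane to the actin cytoskeleton at the neuromuscular junction and stands in for dystrophin elsewhere when dystrophin is missing. Its probe set 92507_at read 304.8 ± 99.4 in dko and 748.1 ± 294 in mdx extraocular muscle, 265.9 ± 29.8 and 493.6 ± 56.6 in leg, and 258.1 ± 36.4 and 643.6 ± 48.5 in heart. In each tissue every mdx array lay above every dko array, and the dko array was lower in all 9 pairs. The log2 differences were -0.93, -0.61 and -0.93 (1.91-, 1.53- and 1.91-fold lower). Across the 3 tissues the mean log2 difference was -0.83 (two-sided exact permutation of genotypes within tissues, p = 0.00025, the smallest that the 8000 assignments can give). That permutation leaves out that arrays of the same number were alike. Exchanging genotypes only within the 9 pairs, a test chosen after the values were seen, gave a two-sided p of 0.00391, the smallest that its 512 assignments can give. Both permutations, here and below, exchange genotypes in each tissue separately. The labels do not say whether the tissues share animals, and if they do, these p-values are too small. Over all probe sets tested, this Utrn difference passed only in extraocular muscle and only with the replicate block (adjusted p = 0.438 without and 0.0333 with it). In leg the values were 0.52 and 0.0602, and in heart 1 and 0.128. The other Utrn probe set, 92508_s_at, did not pass in any tissue. Its log2 differences were -0.97, -0.39 and -0.76, with a mean of -0.70 (two-sided exact permutation within tissues, p = 0.00175, and 0.0156 within pairs). Which part of the transcript either probe set reads, relative to the deleted part of the gene, is not known here.

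Dmd encodes dystrophin, whose loss dko and mdx mice share. Its probe set 93623_at read 300 ± 163 in dko and 469.7 ± 187 in mdx extraocular muscle, 247.4 ± 170 and 315.9 ± 161 in leg, and 251.3 ± 85.6 and 237.7 ± 36.1 in heart. The mean log2 difference across tissues was -0.23 (two-sided exact permutation within tissues, p = 0.258, and 0.0938 within pairs), within the spread between replicates.

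**Figure D2:**
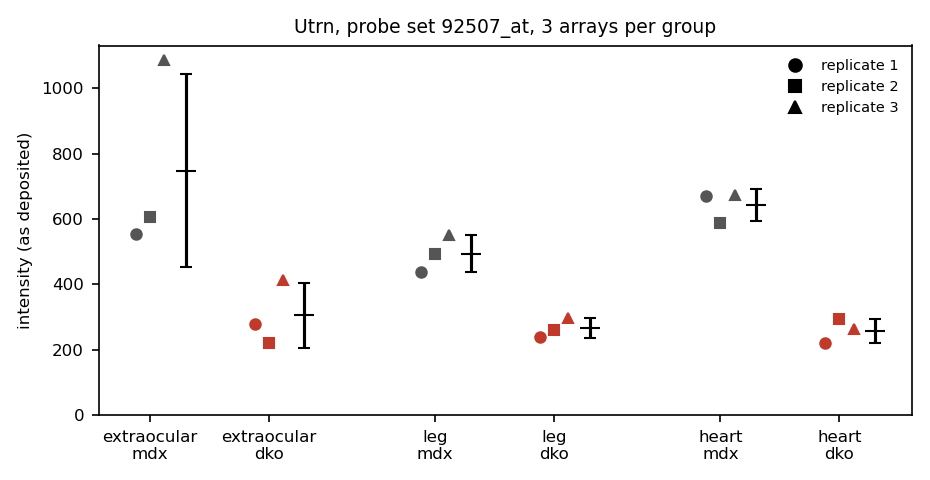
Intensity of the Utrn probe set 92507_at (vertical axis) in the 6 groups, with 1 point per array, shapes for replicate number, and a bar for the mean ± SD (n = 3) beside each group. The dko means of 304.8, 265.9 and 258.1 lie below the mdx means of 748.1, 493.6 and 643.6 in extraocular muscle, leg and heart.

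The second question was how dko extraocular muscle, a muscle group that dystrophin loss is known to spare, differed from its mdx control. The genes that rose were Ctss and Myom2. Ctss, which encodes cathepsin S, a lysosomal protease of macrophages and antigen-presenting cells, read 12080 ± 1790 in dko and 2944 ± 779 in mdx, a log2 difference of 2.00 (3.99-fold higher). Myom2, which encodes the M-band protein M-protein of fast muscle fibres, read 1356 ± 201 and 421.3 ± 63.9, a difference of 1.37 (2.58-fold higher). Each was higher in 3 of 3 pairs, with an adjusted p of 0.0203. With the replicate block 14 probe sets passed, 12 higher and 2 lower, among them Ctss and Myom2. The macrophage lectin Lgals3 (3293 ± 652 in dko and 876.1 ± 510 in mdx), the pore-forming macrophage gene Mpeg1 (4419 ± 401 and 1622 ± 562) and the immune receptor Lilr4b (1578 ± 697 and 399.7 ± 192) rose with the block only. So did the calcium-binding S100a4 (3495 ± 268 and 1478 ± 108), the stretch-responsive Ankrd1 (1478 ± 239 and 418.5 ± 189), and Myl4, the light chain of embryonic and atrial myosin (9896 ± 2770 and 3985 ± 2740), whose other probe set did not pass. These log2 differences ran from 1.15 for S100a4 to 1.86 for Lgals3, and their adjusted p with the block from 0.0316 for S100a4 to 0.0481 for Mpeg1. The largest rise with the block was that of the unnamed probe set 97519_at, 9572 ± 527 against 1869 ± 821 (log2 difference 2.33, adjusted p = 0.0341; 0.125 without the block). The falls with the block were Utrn and Ucp1, the uncoupling protein of brown fat (log2 difference -1.48), which was named after its values were seen.

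Without the block 2 of 8888 probe sets passed in extraocular muscle (limma), 196 had an unadjusted p under 0.05, and 444 would by chance. Leaving out any 1 of the 6 extraocular arrays left 0 probe sets past the threshold, with log2 differences of 1.84 to 2.19 for Ctss and 1.28 to 1.48 for Myom2. With the block, 0 passed without either array numbered 1, 4 without either numbered 2 and 2 without either numbered 3. Without the block, scaling each array to the same 75th percentile also gave 0, as did a fit of the 6 extraocular arrays alone.

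Among 36 gene lists fixed beforehand, 7 were higher and 4 lower in dko extraocular muscle. Macrophage genes moved most clearly: 26 of 29 had a positive difference, with a median log2 difference of 0.64 (adjusted p = 1.28e-27; 0.00707 with an estimated correlation). Of these 29 genes 1 rose and 28 did not pass, while 11 rose adjusted over the list alone. With the block 3 rose (Ctss, Lgals3 and Mpeg1) and 14 rose adjusted over the list alone, among them the lysosomal Cd68 and Lyz2, the pan-leukocyte Ptprc and the monocyte receptor Ccr2. Chemokine, cytokine and complement genes were higher, with a median of 0.14 (adjusted p = 0.00174; 0.0328 with an estimated correlation), and 3 of 19 rose adjusted over the list alone: the monocyte attractants Ccl2 (1.51) and Ccl7 (1.16) and the complement receptor C3ar1 (1.12). The chemokine call ended without mdx array 3 (median 0.0549). Genes of skin and mucosal epithelium were lower, with a median of -0.30 (adjusted p = 6.56e-05; 0.00707 with an estimated correlation), and 2 of 15 fell adjusted over the list alone, Krt19 (-1.33), a keratin of simple epithelia, and Sfn (-1.34), a regulator of keratinocyte division. With block and estimated correlation together 0 lists held their call in extraocular muscle (adjusted p = 0.199 for macrophage, 0.363 for chemokine and 0.121 for skin genes).

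The other lists called in extraocular muscle lost their call with an estimated correlation. Cell division genes were higher in 21 of 25 (median 0.25, adjusted p = 1.87e-06; adjusted p = 0.0656 with an estimated correlation), 0 of them past the threshold alone. With the block Cdk1, Rrm1, Tk1 and Cks2 rose adjusted over the list alone. Extracellular matrix genes had a median of 0.11 (adjusted p = 0.000297; adjusted p = 0.256 with an estimated correlation), and the call ended without dko array 3 (0.0591). Regeneration and embryonic muscle genes had a median of 0.0372 (adjusted p = 0.00293; adjusted p = 0.0984 with an estimated correlation). The call ended without mdx array 1 (-0.00248) or dko array 3 (0.167). Glucocorticoid and fasting response genes had a median of 0.20 (adjusted p = 0.0086; adjusted p = 0.413 with an estimated correlation), and the call ended without mdx array 1 (0.115), dko array 1 (0.186), mdx array 3 (0.211) or dko array 3 (0.0955). Cardiac stress response genes had a median of 0.0955 (adjusted p = 0.0159; adjusted p = 0.203 with an estimated correlation; 0.206 with the block), and the call ended without mdx array 1 (-0.0599), dko array 1 (0.0876) or dko array 3 (-0.0954).

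Endothelial genes in extraocular muscle were lower in 17 of 19 (median -0.12, adjusted p = 0.00872; adjusted p = 0.054 with an estimated correlation), and adipocyte genes had a median of -0.28 (adjusted p = 0.00362; adjusted p = 0.325 with an estimated correlation). Genes of cardiac muscle had a median of -0.22 (adjusted p = 0.0159; adjusted p = 0.413 with an estimated correlation). The endothelial call ended without dko array 1 (-0.125) or mdx array 3 (-0.0942), the adipocyte call without dko array 2 (-0.121), and the cardiac muscle call without dko array 2 (-0.171), mdx array 3 (-0.218) or dko array 3 (-0.223). The remaining 25 lists had adjusted p from 0.253 (retina and eye pigment) to 0.924 (lung). Among them were the dystrophin-associated complex (0.82), the neuromuscular junction (0.279), fast (0.903) and slow (0.52) contractile proteins, calcium handling (0.616), oxidative phosphorylation (0.38) and ribosomal proteins (0.345). Median and mean differed in sign for the dystrophin-associated complex (0.0772 and -0.0206), the neuromuscular junction (-0.0528 and 0.164), lung (0.0174 and -0.027), fast contractile proteins (0.0015 and -0.0572) and heat shock and oxidative stress (-0.0101 and 0.0152).

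The third question was the same contrast in leg muscle, which dystrophin loss damages. The clearest change was in the genes of slow muscle fibres. Myh7, the myosin heavy chain of slow fibres, also made in heart, read 16270 ± 1300 in dko and 867.8 ± 982 in mdx, a log2 difference of 4.40 (21.1-fold higher, adjusted p = 0.000559; higher in 3 of 3 pairs). The other Myh7 probe set, 161547_f_at, read 306.9 and 199.6 and did not pass. With the replicate block, genes of the same fibre type rose beside it: Myl2, the slow regulatory light chain (19610 ± 5640 against 1294 ± 1100, log2 difference 4.05, adjusted p = 0.00193); Tnnc1, slow troponin C (11850 ± 2170 against 2018 ± 569, 2.48, adjusted p = 0.000301); and Tnnt1, slow troponin T (23320 ± 4340 against 5921 ± 671, 1.94, adjusted p = 0.0175). Atp2a2, the slow-fibre calcium pump, read 5891 ± 1550 against 1730 ± 651 (1.70, adjusted p = 0.0141). Without the block their adjusted p ran from 0.0535 for Tnnc1 to 0.402 for Myl2. The other Tnnt1 probe set, 101383_at, had a log2 difference of 0.74 and did not pass (adjusted p = 0.0581 with the block). Leaving out either leg array numbered 2 ended the blocked call of Atp2a2 (log2 difference 1.53), and that of Tnnt1 ended without either array of any number (1.89 to 2.00).

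Of the 15 genes in the list of slow contractile proteins, 1 rose and 14 did not pass. Adjusted over the list alone 7 rose, and with the block 7 rose over all probe sets, among them the slow tropomyosin Tpm3 (1.60) and slow troponin I, Tnni1 (0.98). The list had a median log2 difference of 0.68 (adjusted p = 1.14e-11; 0.00828 with an estimated correlation; 0.0425 with block and estimated correlation together). The fast contractile list had a median of 0.22 and was not called (adjusted p = 0.188). Acta1, skeletal alpha-actin, rose with the block only (adjusted p = 0.0158; 0.861 without it), but its mdx readings were 256.1, 247.7 and 6656.3 on arrays 1, 2 and 3 and its dko readings 1281.8, 1915 and 20656, so that the groups overlapped.

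Genes of immature and regenerating fibres were also higher in dko leg muscle. Myh3, the embryonic myosin heavy chain, read 8707 ± 2770 in dko and 1981 ± 604 in mdx (log2 difference 2.04, 4.12-fold higher, adjusted p = 0.023; higher in 3 of 3 pairs). With the block Myh8, the perinatal myosin, rose from 2181 ± 475 in mdx to 4779 ± 960 in dko (1.08), and Myl4 from 7433 ± 1460 to 17290 ± 2260 (1.21), although the other Myl4 probe set, 100828_at, had the opposite sign (-0.43, not past the threshold). The acetylcholine receptor subunits Chrna1 (3012 ± 594 in mdx, 5484 ± 1270 in dko) and Chrnd (298.3 ± 60.9 and 773.7 ± 96) rose with the block, by 0.82 and 1.02. Tubb2a, a beta-tubulin, read 10110 ± 1140 in dko and 4166 ± 497 in mdx (1.25, adjusted p = 0.0475), and its other probe set, 161614_r_at, had the opposite sign (-0.23, not past the threshold). The list of regeneration and embryonic muscle had a median of 0.59, with 19 of 22 genes positive (adjusted p = 3.32e-08; 0.00828 with an estimated correlation, but 0.0811 with block and estimated correlation together). In that list 1 gene rose and 21 did not pass, and 7 rose adjusted over the list alone. With the block 12 rose and 2 fell adjusted over the list alone, the falls being the growth inhibitor Mstn (-0.67) and the filament protein Vim (-0.56). The neuromuscular junction list had a median of 0.24 (adjusted p = 0.00583; 0.0342 with an estimated correlation, but 0.126 with block and estimated correlation together), and 2 of its 13 genes rose adjusted over the list alone. Cell division genes had a median of 0.16 (adjusted p = 0.00169; adjusted p = 0.261 with an estimated correlation), with Cdk1 (1.24) and Cks2 (1.37) rising with the block.

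The lists of matrix, macrophage and chemokine genes were higher in dko leg muscle. Postn encodes periostin, a matrix protein of activated fibroblasts, and read 21420 ± 4370 in dko and 8938 ± 1860 in mdx (log2 difference 1.24, 2.37-fold higher, adjusted p = 0.0475; higher in 3 of 3 pairs). With the block the stromelysin Mmp3 (2410 ± 693 and 684.4 ± 25.5, 1.57) and elastin, Eln (14790 ± 3140 and 6152 ± 1690, 1.25), rose. The other Eln probe set, 92207_at, did not pass (0.85). The matrix list had a median of 0.52, with 40 of 45 genes positive (adjusted p = 1.4e-15; 0.00828 with an estimated correlation, but 0.0811 with block and estimated correlation together). Of the 45, 1 rose and 44 did not pass. Adjusted over the list alone 12 rose, and with the block 10 rose over all probe sets, Col5a2 (1.02) and Bgn (0.94) among them. Macrophage genes had a median of 0.78 (adjusted p = 1e-18; 0.00828 with an estimated correlation, but 0.126 with block and estimated correlation together), with 28 of 29 positive. Of these, 0 rose over all probe sets without the block, although 16 rose adjusted over the list alone. Those that rose with the block were the tetraspanin Cd53 (2589 ± 1130 and 736.2 ± 926, 2.00), the growth factor receptor Csf1r (4789 ± 1390 and 2322 ± 781, 1.00), and the complement genes C1qb (8576 ± 5120 and 3559 ± 2360, 1.25) and C1qc (0.91). The Cd53 and C1qb groups overlapped, and other probe sets of C1qb (162276_i_at, -0.59) and Csf1r (161832_r_at, -0.0078) had the opposite sign without passing.

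The chemokine list in leg had a median of 0.42 (adjusted p = 8.64e-06; 0.00828 with an estimated correlation, but 0.0864 with block and estimated correlation together), and Ccl8, a monocyte attractant, rose with the block (3303 ± 484 and 975.7 ± 607, 1.79). Antigen presentation and interferon genes had a median of 0.23 (adjusted p = 0.00196; adjusted p = 0.33 with an estimated correlation), with the class II genes H2-Ab1 (4096 ± 1120 and 1767 ± 319, 1.12) and H2-Aa (8248 ± 2500 and 3994 ± 2590, 1.14, overlapping groups) rising with the block. That list call ended without mdx array 1 (0.197) or dko array 3 (0.201). Cardiac stress response genes had a median of 0.32 (adjusted p = 1.62e-06; 0.00828 with an estimated correlation, but 0.103 with block and estimated correlation together). Of its 21 genes 2 rose, and Myh7 and Postn are members. Several lists of other cell types were not called in dko leg muscle: endothelium had a median of -0.16 (adjusted p = 0.198), erythroid cells -0.23 (0.0974), adipocytes -0.0844 (0.428), T cells -0.0724 (0.9) and smooth muscle 0.0383 (0.459).

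Few genes fell in dko leg muscle. Ighm, the heavy chain of immunoglobulin M, read 308.9 ± 27.1 in dko and 1408 ± 585 in mdx on 93584_at (log2 difference -1.67, 3.18-fold lower, adjusted p = 0.0333; lower in 3 of 3 pairs). A second Ighm probe set, 93583_s_at, fell with the block only (-1.18, adjusted p = 0.0289), and its other 3 probe sets were lower by log2 differences of -0.16 to -0.41 without passing. The B-cell list was not called (median -0.18, adjusted p = 0.265). With the block the glycogen genes Phkg1 (4528 ± 1020 and 8162 ± 1070, -0.84), a phosphorylase kinase subunit, and Slc37a4 (3629 ± 375 and 6821 ± 1520, -0.86), the glucose-6-phosphate transporter, fell, as did the epoxide hydrolase Ephx2 (265.2 ± 180 and 685.1 ± 147, -1.07). Lists of energy metabolism were lower by small amounts. Oxidative phosphorylation had a median of -0.11 (adjusted p = 0.0241; adjusted p = 0.706 with an estimated correlation), with 0 of 63 genes past the threshold. The call ended without dko array 2 (-0.0212), and the median was positive without mdx array 3 (0.0866). The tricarboxylic acid cycle had a median of -0.22 (adjusted p = 0.0468; adjusted p = 0.33 with an estimated correlation), and the call ended without dko array 1 (-0.242), dko array 2 (-0.214) or mdx array 3 (-0.0822). The 1 member of that list past the threshold with the block, the isocitrate dehydrogenase Idh2, rose (5935 ± 2460 and 3694 ± 1240, 0.63, adjusted p = 0.0369; higher in 3 of 3 pairs, overlapping groups). Fatty acid oxidation was lower with the block only (median -0.16, adjusted p = 0.0152; 0.0643 without it and 0.236 with block and estimated correlation together). Limb and trunk patterning genes had a median of -0.28 (adjusted p = 0.00583; adjusted p = 0.365 with an estimated correlation) and tendon and cartilage genes -0.43 (adjusted p = 0.0225; adjusted p = 0.33 with an estimated correlation). Both of these calls ended without mdx array 1 (-0.127 and -0.544) or dko array 3 (-0.131 and -0.316). The lists not called in leg had adjusted p from 0.0643 to 0.9. The dystrophin-associated complex had a median of -0.0146 (0.552), with 1 fall adjusted over the list alone, the neuronal nitric oxide synthase Nos1 (-1.16). Median, mean or test differed in sign for skin epithelium, cardiac muscle, calcium handling, glycolysis, and heat shock, whose medians lay between -0.124 and 0.0127.

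In leg 5 of 8888 probe sets passed without the block (4 higher, 1 lower; limma) and 107 with it (90 higher, 17 lower). An unadjusted p under 0.05 was found for 556 and 1585, against 444 by chance. Without the block the count was 1 when mdx array 1, mdx array 2, dko array 2 or dko array 3 was left out, 3 without dko array 1 and 17 without mdx array 3. With the block it was 31 without either array numbered 1, 8 without either numbered 2 and 60 without either numbered 3. A fit of the 6 leg arrays alone gave 0 without the block and 1 with it. The call of Myh7 was kept in all 6 fits that left out 1 leg array. Those of Myh3, Tubb2a, Postn and Ighm ended in 4 to 5 of the 6, at log2 differences of 1.80 to 2.11 for Myh3, 1.15 to 1.31 for Tubb2a, 1.11 to 1.22 for Postn and -1.83 to -1.38 for Ighm.

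**Figure D3:**
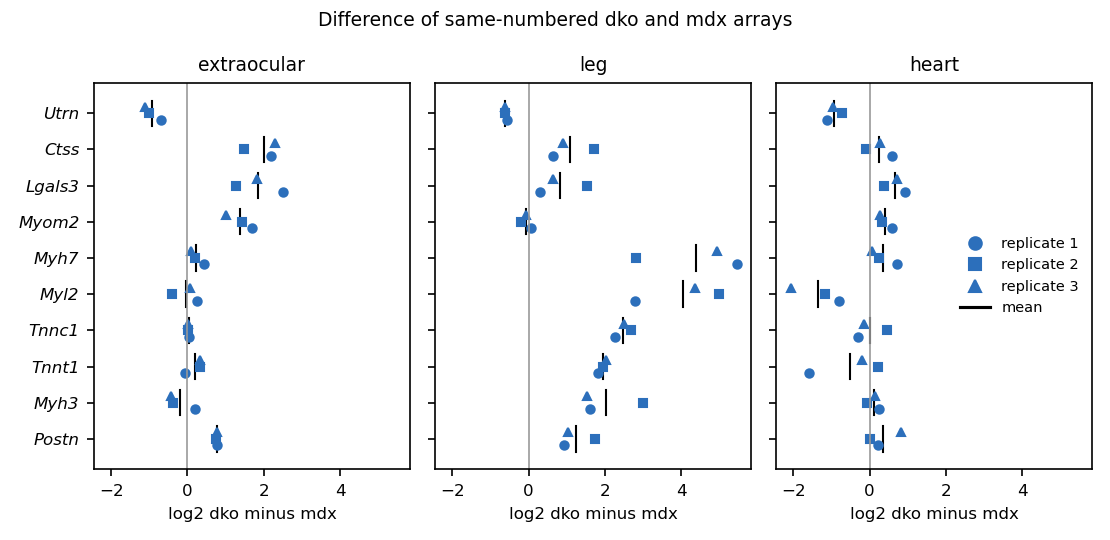
Log2 difference of dko over mdx (horizontal axis) for 10 genes (vertical axis) in the 3 tissues, with 1 point for each replicate number and a black line at the mean. The means for Myh7, Myl2 and Tnnc1 are 4.40, 4.05 and 2.48 in leg, 0.23, -0.0282 and 0.0302 in extraocular muscle and 0.34, -1.34 and 0.0107 in heart.

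The fourth question was whether the heart, which weakens later than leg muscle in mdx mice, differed at this age. No probe set passed in heart, with or without the replicate block (limma, 0 of 8888; 130 and 494 with an unadjusted p under 0.05, against 444 by chance). Without the block the 5 probe sets with the smallest unadjusted p were all lower in dko and none passed. They were Utrn 92507_at; Thrsp, a regulator of lipid synthesis (1329 ± 460 in dko and 2743 ± 595 in mdx, log2 difference -0.98, adjusted p = 1); the unnamed 93086_at (995.8 ± 230 and 4905 ± 3190, -1.94); and the immunoglobulin probe sets of Igkv6-23 (597.2 ± 284 and 1844 ± 981, -1.36) and Ighm (93583_s_at, 1727 ± 441 and 3424 ± 766, -0.93). With the block the smallest was that of the unnamed 101869_s_at (4611 ± 6700 and 11550 ± 15500, -1.48, adjusted p = 0.055 with the block and 1 without; lower in 3 of 3 pairs, with overlapping groups). Utrn 92507_at and the unnamed 102906_at (-1.14) followed, each at 0.128, then Ucp1 (-1.14) and Afp (-0.84), each at 0.361. Leaving out mdx array 3 without the block let 1 probe set pass.

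As groups, 3 lists were lower and 1 higher in dko heart, and each lost its call with an estimated correlation. Adipocyte genes had a median of -0.31 (adjusted p = 6.46e-07; adjusted p = 0.138 with an estimated correlation). Of 13, 0 fell over all probe sets and 3 fell adjusted over the list alone: the fat-cell hormone Retn (-1.31), the desaturase Scd1 (-1.66) and Thrsp (-0.98). Antigen presentation and interferon genes were lower in 25 of 28 (median -0.30, adjusted p = 6.46e-07; adjusted p = 0.138 with an estimated correlation). With the block 6 of them fell adjusted over the list alone, H2-DMb1 (-0.94) and Isg15 (-0.82) among them. All 7 B-cell genes were lower (median -0.30, adjusted p = 1.67e-05; adjusted p = 0.138 with an estimated correlation), and Cd79b (-1.05) and Ighm (-0.93) fell adjusted over the list alone. Glucocorticoid and fasting response genes were higher (median 0.21, adjusted p = 0.00918; adjusted p = 0.73 with an estimated correlation; 0.0542 with the block), a call that ended without mdx array 1 (0.171), dko array 1 (0.157), mdx array 3 (0.163) or dko array 3 (0.143). Without mdx array 3 the number of lists called was 8. The other 32 lists had adjusted p from 0.259 to 0.993, among them macrophage (median -0.0122, 0.993), extracellular matrix (0.0466, 0.259), cardiac stress response (0.0466, 0.278), cardiac muscle (-0.00514, 0.761) and erythroid cells (-0.246, 0.259). Median and mean differed in sign in heart for slow contractile proteins (0.0936 and -0.124) and for macrophage genes (-0.0122 and 0.00359), among others of small size.

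**Figure D4:**
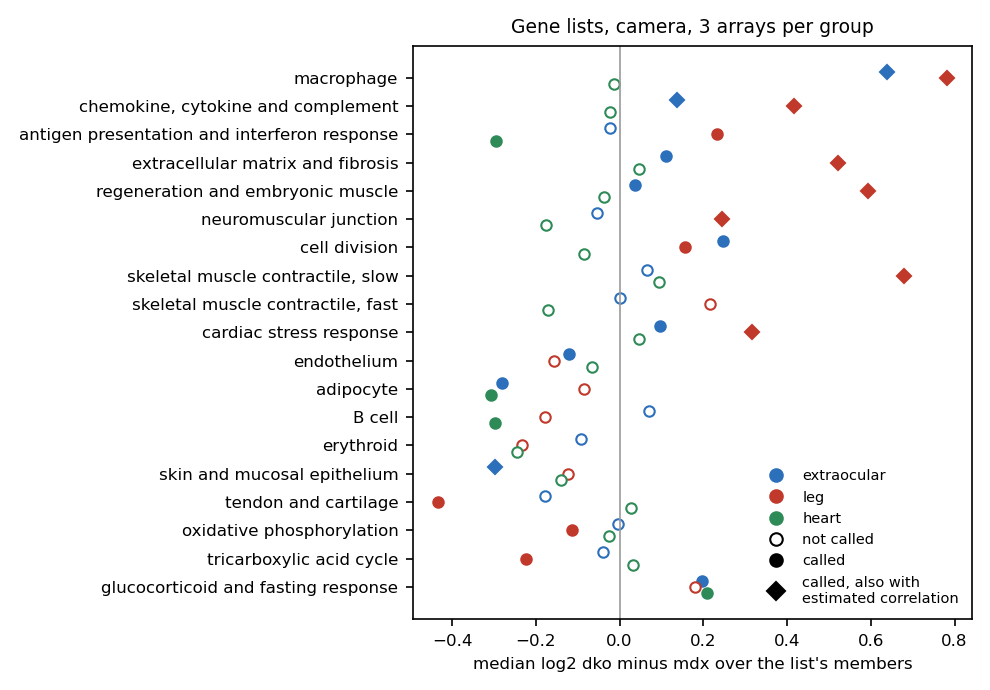
Median log2 difference of dko over mdx (horizontal axis) for 19 of the 36 gene lists (vertical axis) in the 3 tissues, with open circles where the list was not called, filled circles where it was, and diamonds where the call held with an estimated correlation. The macrophage median is 0.64 in extraocular muscle, 0.78 in leg and -0.0122 in heart, and the slow contractile median in leg is 0.68.

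The fifth question was whether the 3 tissues differed in their response, which was tested as the difference between their dko and mdx changes. No probe set passed without the replicate block (limma, 0 of 8888 in each of the 3 tests; 180, 259 and 124 with an unadjusted p under 0.05). With the block the leg response differed for slow-fibre genes: the change in Tnnc1 was lower in extraocular muscle by a log2 difference of -2.45 (adjusted p = 0.0084) and in heart by -2.47 (0.00617), and that in Myl2 by -4.07 (0.0481) and -5.39 (0.00617). The change in Myh7 was smaller in heart than in leg by -4.06 (0.0441). The potassium-channel subunit gene Kcne1l (-1.95, 0.0208) and the unnamed 98501_at (-1.54, 0.0441) rose in leg and not in heart. For Acta1 the difference was -3.10 (0.0208), from a change of 1.90 in leg and one of -1.19 in heart that did not pass (adjusted p = 0.433 with the block). The heart change of Myl2 did not pass either (-1.34, 0.634). Heart readings of Myl2 were uneven, 3015 ± 3760 in dko and 11460 ± 16900 in mdx, so the size of its -5.39 is uncertain. The Acta1 difference rests in part on the low mdx leg readings given above. For 98501_at the difference between extraocular muscle and leg was -1.68 (0.0481). These made 3 probe sets for extraocular muscle against leg and 6 for heart against leg, and 0 for extraocular muscle against heart (530 with an unadjusted p under 0.05). In the first of these tests 0 passed without any 1 of the extraocular arrays or either leg array numbered 3. In the second 2 passed without either leg array numbered 1 or either heart array numbered 3. Without the block 2 passed in the first test without extraocular mdx array 1 and 1 without leg mdx array 2, and 1 passed in the second without leg mdx array 2 or heart mdx array 2.

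Among lists, the macrophage response differed between heart and leg (median difference -0.73, adjusted p = 2.51e-14; 0.0255 with an estimated correlation) and between extraocular muscle and heart (0.54, adjusted p = 1.51e-18; adjusted p = 0.0515 with an estimated correlation). It was not called between extraocular muscle and leg (median -0.14, adjusted p = 0.787). Slow contractile genes changed less in extraocular muscle than in leg (median -0.78, adjusted p = 8.71e-10; adjusted p = 0.068 with an estimated correlation and 0.0457 with block and estimated correlation together) and less in heart (-0.63, adjusted p = 4.23e-10; 0.0226 with an estimated correlation). Heart against leg gave 13 lists, 8 of them with an estimated correlation: regeneration (-0.63), neuromuscular junction (-0.51), extracellular matrix (-0.42), chemokines (-0.45), antigen presentation (-0.57) and cardiac stress response (-0.29), beside the macrophage and slow lists. With block and estimated correlation together 0 lists held between heart and leg (adjusted p = 0.0659 to 0.151 for these 8). The other 5 were called only with the preset correlation: cell division (-0.27; adjusted p = 0.165 with an estimated correlation), adipocyte (-0.16; adjusted p = 0.473 with an estimated correlation), tendon and cartilage (0.56; adjusted p = 0.234 with an estimated correlation), fatty acid oxidation (0.26; adjusted p = 0.46 with an estimated correlation), and limb patterning (0.22; adjusted p = 0.46 with an estimated correlation).

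Extraocular muscle against leg gave 6 lists and extraocular muscle against heart 8, of which 0 held with an estimated correlation. Beside slow contractile genes, the response was smaller in extraocular muscle than in leg for extracellular matrix (median -0.37), regeneration (-0.30), antigen presentation (-0.30), and cardiac stress response (-0.20). Skin epithelium also differed (-0.43), through its fall in extraocular muscle, and was not called in leg. Over the 6 lists the adjusted p was 0.068 to 0.359 with an estimated correlation. This count was 10 without extraocular mdx array 1, and 3 without leg mdx array 1 or extraocular mdx array 3. Against heart, the change in extraocular muscle was larger for macrophage, cell division (0.30), chemokine (0.24) and regeneration (0.13) genes. The differences for B-cell (0.53) and antigen presentation (0.27) genes went with their falls in heart, as neither list was called in extraocular muscle. Skin epithelium (-0.17) and cardiac muscle (-0.41) were lower through falls in extraocular muscle. Over the 8 lists the adjusted p was 0.0515 to 0.525 with an estimated correlation. That count was 15 without heart dko array 1, 13 without heart mdx array 3, 5 without extraocular mdx array 1 or extraocular dko array 2, and 4 without heart mdx array 2.

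The probe sets that passed in extraocular muscle and in leg shared 0 members without the block. With it they shared 4 rises, in Kcne1l, Ms4a6c, Myl4 and S100a4, where 0.122 were expected. Kcne1l read 827.9 in dko and 260.5 in mdx extraocular muscle and 1430 ± 580 and 329 ± 300 in leg. Across probe sets, which are not independent replicates, the dko and mdx changes correlated at 0.235 between extraocular muscle and leg, 0.0827 between extraocular muscle and heart and 0.0694 between leg and heart.

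The last question was how the muscles of the mdx controls differed from each other before any change in dko. In mdx extraocular muscle, compared with mdx leg, genes of slow and embryonic myosins were higher: Myh7 read 17690 ± 5940 and 867.8 ± 982 (log2 difference 4.46, 22.1-fold, adjusted p = 3.24e-05) and Myh3 16680 ± 6020 and 1981 ± 604 (7.68-fold). Myom2 was far lower, 421.3 ± 63.9 against 11620 ± 1960 (-4.32, 19.9-fold lower, adjusted p = 3.62e-09), as were the stretch-responsive Ankrd1 (418.5 ± 189 and 5814 ± 2810, 9.91-fold lower), its relative Ankrd2 (1723 ± 193 and 10830 ± 4550, 5.54-fold lower) and the calcium-channel subunit Cacng1 (1096 ± 86.9 and 10190 ± 4390, 7.76-fold lower). The limb patterning genes Hoxc9 (149.3 ± 13.9 and 1056 ± 188, 3.84-fold lower) and Hoxa10 (18.77 ± 12.5 and 481.9 ± 132, 3.46-fold lower) were lower too. Genes of other tissues were higher: Bpifa2, a secreted protein of salivary glands (9003 ± 675 and 222.4 ± 101, 24.1-fold), the fat-cell hormone Adipoq (8117 ± 2080 and 781.4 ± 501, 9.31-fold) and the myelin genes Pmp22 (11290 ± 2060 and 1921 ± 89.5, 5.44-fold) and Mbp (5960 ± 1720 and 974.5 ± 268, 5.32-fold; its other probe set did not pass). Each of these was apart in 3 of 3 against 3 of 3 arrays, which chance gives for 10% of probe sets. Acta1 was the largest rise (26600 ± 3560 and 2387 ± 3700, 25.1-fold), resting on low readings on leg arrays 1 and 2. Its call ended without mdx leg array 1 (log2 difference 3.98) or mdx leg array 2 (3.97).

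Between mdx extraocular muscle and leg 357 of 8888 probe sets passed (228 higher, 129 lower; 268 by at least 2-fold), and 1106 with a block for replicate number. The count was 178 without leg mdx array 2, 181 without extraocular mdx array 2, 222 without extraocular mdx array 3, 226 without leg mdx array 1 and 230 without extraocular mdx array 1. Of the lists 8 were higher and 2 lower. All 13 adipocyte genes were higher, 7 of them past the threshold (median 1.11, adjusted p = 1.75e-10; 0.0389 with an estimated correlation), and lacrimal and Harderian gland genes had a median of 0.94 (2 of 6 rose, 4 did not pass; adjusted p = 0.00122; 0.0389 with an estimated correlation). With block and estimated correlation together neither held (0.113 and 0.167). The other calls held only with the preset correlation. They were higher values of slow contractile proteins (0.94; adjusted p = 0.399 with an estimated correlation), smooth muscle (0.60; 0.127), endothelium (0.44; 0.0559), skin epithelium (0.35; 0.13), nerve and Schwann cells (0.34; 0.127) and fatty acid oxidation (0.34; 0.426), and lower values of macrophage genes (-0.46; 0.231) and of ubiquitin, proteasome and lysosome genes (-0.21; 0.451). Of these, macrophage, smooth muscle and nerve calls were kept whichever array was left out, and that of endothelium ended without extraocular mdx array 3 (0.37). The slow contractile call ended without leg mdx array 2 (0.719) or extraocular mdx array 3 (0.511), the skin call without extraocular mdx array 1 (0.311), extraocular mdx array 2 (0.278) or leg mdx array 3 (0.192), the fatty acid call without leg mdx array 1 (0.232), leg mdx array 2 (0.276) or extraocular mdx array 3 (0.177), and the ubiquitin call without extraocular mdx array 1 (-0.123) or leg mdx array 3 (-0.125). The 26 lists not called had adjusted p from 0.07 to 0.948.

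The mdx heart differed from mdx leg in the contractile proteins of cardiac and skeletal muscle. Higher in heart were Myh6, a myosin heavy chain of heart muscle (35190 ± 30900 against 78.9 ± 22, 100-fold, adjusted p = 4.9e-06), and Myl7, the atrial light chain (25080 ± 10300 against 75.77 ± 15.2, 97.9-fold, adjusted p = 7.9e-10). So were cardiac troponin I, Tnni3 (72.8-fold), the cardiac calcium release channel Ryr2 (16050 ± 4670 against 122.6 ± 92.4, 56.3-fold) and the natriuretic peptide gene Nppb (26960 ± 9480 against 339.4 ± 114, 52.5-fold). Lower in heart were Pvalb, the fast-fibre calcium buffer parvalbumin (153 ± 52.7 against 34090 ± 10200, 105-fold lower, adjusted p = 7.9e-10), fast troponin T, Tnnt3 (102-fold lower), Myh1 (89.7-fold lower) and the skeletal calcium release channel Ryr1 (193.6 ± 69.2 against 28330 ± 8250, 77.9-fold lower, adjusted p = 1.04e-10). The other Pvalb probe set, 96719_i_at, had the opposite sign (1.64) and did not pass. The limb patterning gene Tbx15 was 17.5-fold lower (65.17 ± 41.9 against 3896 ± 850), the acetylcholine receptor subunit Chrna1 13.6-fold lower (63.77 ± 15.1 against 3012 ± 594), and the beta-oxidation enzyme Decr1 3.16-fold higher (6091 ± 338 against 1813 ± 91.9).

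Between mdx heart and leg 886 probe sets passed (448 higher, 438 lower; 647 by at least 2-fold), and 2026 with a block for replicate number. Of the lists 6 were higher and 8 lower. Cardiac muscle genes had a median of 2.41, with 13 risen, 1 fallen and 9 not past the threshold (adjusted p = 3.67e-14; 0.012 with an estimated correlation). Fatty acid oxidation had a median of 1.00, with 12 risen, 1 fallen and 11 not past it (adjusted p = 8.71e-09; 0.0402 with an estimated correlation), and endothelium 0.85, with 8 of 19 risen (adjusted p = 0.00014; 0.0102 with an estimated correlation). Regeneration and embryonic muscle genes were lower (median -1.15, 1 risen and 13 fallen of 22, adjusted p = 2.52e-08; 0.0102 with an estimated correlation). With block and estimated correlation together the cardiac muscle call was lost (adjusted p = 0.132), and the other 3 held (0.0275). The other 10 calls held only with the preset correlation without the block: fast contractile proteins (-2.16; adjusted p = 0.178 with an estimated correlation), neuromuscular junction (-0.50; 0.0554), limb patterning (-0.39; 0.315, and 0.0275 with block and estimated correlation together), ubiquitin (-0.38; 0.271), glycolysis (-0.34; 0.556), tendon (-0.44; 0.335), extracellular matrix (-0.18; 0.488), adipocyte (0.97; 0.254), cardiac stress response (0.61; 0.207) and antigen presentation (0.36; 0.449). Leaving out 1 array ended the calls of tendon (without leg mdx array 1, heart mdx array 2 or heart mdx array 3; -0.407, -0.42 and -0.275), antigen presentation (without leg mdx array 1, leg mdx array 2, heart mdx array 2 or heart mdx array 3; 0.243, 0.263, 0.378 and 0.289), extracellular matrix (without heart mdx array 2 or leg mdx array 3; -0.216 and -0.119) and glycolysis (without heart mdx array 1, heart mdx array 2 or leg mdx array 3; -0.233, -0.225 and -0.0682). The 22 lists not called had adjusted p from 0.0602 (macrophage) to 0.968. The tricarboxylic acid cycle was called with the block only (median 0.12, adjusted p = 0.0425; 0.145 without it).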

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

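The tests of other splits below were set out beforehand, except those with the replicate block and those of lists that keep pairs parted. Those, and the tests of cell share, blood and a signal ceiling, were chosen only after the results were seen.

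The change from mdx to dko differed between tissues by a direct test of the difference. With the replicate block, the change was lower in extraocular muscle than in leg for Tnnc1 (log2 difference -2.45), Myl2 (-4.07) and 98501_at (-1.68). It was lower in heart than in leg for Acta1 (-3.10), Kcne1l (-1.95), Tnnc1 (-2.47), Myl2 (-5.39), 98501_at (-1.54) and Myh7 (-4.06). Without the block none of these differences passed. For Myl2, Tnnc1 and Myh7, which read lowest in leg among mdx tissues, the change in leg was 4.05, 2.48 and 4.40. In extraocular muscle it was -0.0282, 0.0302 and 0.23, and in heart -1.34, 0.0107 and 0.34. The heart changes of Acta1 and Myl2 did not pass. Exchanging genotypes within pairs gave 32 splits. For extraocular muscle against leg 6 called at least the 3 of the real split. The highest other, 151, exchanged all pairs of 1 tissue, so it tests the sum of the 2 changes. The highest of the remaining 30 called 7, and 4 called at least 3. For heart against leg 4 of 32 called at least 6. The highest other, 7, again exchanged all pairs of 1 tissue. Of the remaining 30 the highest called 6, and 2 did so. For extraocular muscle against heart 32 of 32 called at least 0, the highest other, 4, being that split too. Splits that exchange only some pairs, here and for lists, still hold part or all of a tissue's change. They are no null for the difference, so chance was left open.

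Among lists, extraocular muscle against leg gave regeneration (median difference -0.299), extracellular matrix (-0.369), antigen presentation (-0.298), skin epithelium (-0.43), slow contractile proteins (-0.782) and cardiac stress response (-0.198). All 6 lost their call with an estimated correlation (adjusted p = 0.068 to 0.359). With the preset correlation the calls of extracellular matrix and slow contractile proteins were kept whichever array was left out. Regeneration lost its call without extraocular dko array 1 (-0.267), leg mdx array 1 (-0.238), extraocular mdx array 3 (-0.199) or leg dko array 3 (-0.236). Antigen presentation lost it without leg mdx array 1 (-0.202), extraocular mdx array 3 (-0.139) or leg dko array 3 (-0.201). Cardiac stress response lost it without leg mdx array 1 (-0.243), extraocular dko array 2 (-0.122), extraocular mdx array 3 (-0.268) or leg dko array 3 (-0.25). Skin epithelium lost it without leg dko array 1 (-0.194), extraocular mdx array 2 (-0.361) or leg mdx array 3 (-0.235). Of 100 splits drawn, 61 called at least the 6 real lists and the highest other called 17. The 100 splits, here and for the other 2 comparisons, regroup arrays without keeping pairs of the same number, and some test the sum of the 2 changes. Of the 32 splits that keep all pairs parted 19 called at least as many lists, the highest other calling 17. That was the split that exchanges all pairs of 1 tissue, and of the remaining 30 the highest called 15 and 17 called at least 6. Chance was left open for the lists, and for the 0 probe sets found without the block, which every split reaches (16 at most).

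Heart against leg gave neuromuscular junction (-0.508), regeneration (-0.631), cell division (-0.265), extracellular matrix (-0.42), macrophage (-0.731), chemokines (-0.447), antigen presentation (-0.572), adipocyte (-0.158), tendon and cartilage (0.557), slow contractile proteins (-0.627), cardiac stress response (-0.289), fatty acid oxidation (0.256) and limb patterning (0.218). Of these 8 held with an estimated correlation, and 0 with block and estimated correlation together. With the preset correlation, leaving out 1 array ended the calls of adipocyte (7 arrays, medians -0.3 to -0.0415), fatty acid oxidation (6 arrays, 0.0276 to 0.229) and limb patterning (4 arrays, 0.0794 to 0.165). The tendon and cartilage call ended without heart dko array 1 (0.483), leg mdx array 1 (0.496) or heart mdx array 2 (0.471). Of 100 splits, 11 called at least the 13 real lists and the highest other called 18. Of the 32 that keep pairs parted 2 did, the highest other calling 13, and exchanging all pairs of 1 tissue called 10. Chance was left open for the lists, and for the 0 probe sets without the block (7 at most in other splits).

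Extraocular muscle against heart gave regeneration (0.129), cell division (0.302), macrophage (0.538), chemokines (0.241), antigen presentation (0.265), B cell (0.53), skin epithelium (-0.169) and cardiac muscle (-0.408). All 8 lost their call with an estimated correlation (adjusted p = 0.0515 to 0.525). With the preset correlation the macrophage and cell division calls were kept whichever array was left out. Regeneration lost its call without any 1 of 7 arrays (0.0736 to 0.22), skin epithelium without any 1 of 6 (-0.252 to -0.0572), cardiac muscle without any 1 of 6 (-0.368 to -0.0926) and chemokines without any 1 of 5 (0.135 to 0.311). Antigen presentation lost it without extraocular mdx array 1 (0.187), heart mdx array 2 (0.241) or extraocular dko array 3 (0.175), and B cell without extraocular mdx array 3 (0.302). Of 100 splits, 24 called at least the 8 real lists and the highest other called 12. Of the 32 that keep pairs parted 7 did, the highest other calling 11. Exchanging all pairs of 1 tissue called 11, and of the remaining 30 the highest also called 11 and 5 called at least 8. Chance was left open for the lists, and for the 0 probe sets without the block (3 at most in other splits).

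The first pattern weighed was the rise of slow-fibre contractile genes in dko leg, where 7 of 15 list members were called with the block. A ceiling on the signal of bright probe sets would lower the mdx leg readings of these genes on arrays 1 and 2 below those on array 3. Their median log2 gap was 0.255, below the changes of 0.98 to 4.40, which argues against that ceiling as the cause. A larger share of slow muscle in the dko leg samples could also raise the genes, and it cannot be told apart from a change of the fibres themselves: the 8 members not called had a median of 0.337 and went both ways, from -0.46 for Mb to 0.68 for Ankrd2, and the labels do not name the leg muscle. Lists that may depend on where a sample was taken were lower in dko leg too, limb and trunk patterning (median -0.275; Hoxa13 -1.03, past the threshold only with the block over the list alone) and tendon and cartilage (-0.43), but both lost their call with an estimated correlation (adjusted p = 0.365 and 0.33). Sampling of another part of the leg was therefore not excluded. A change of fibre type in dko leg muscle stays open as a hypothesis.

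The second pattern weighed was the rise of macrophage genes in dko extraocular muscle (median 0.64) and leg (0.78). A lower share of muscle RNA would raise the markers of every other cell type alike, but the endothelial list had medians of -0.12 and -0.156, which argues against it. Blood left in the samples would raise erythroid genes, whose medians were -0.0918 and -0.233, which argues against it as well. More macrophage RNA in dko muscle may be the source and stays open as a hypothesis, since neither test separates more macrophages from more RNA per macrophage.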

How the results depend on the processing

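The block common to all arrays, the fits of numbers 1 and 2 only, and the block combined with another setting, the estimated correlation included, were chosen only after the results were seen. The other settings were set out beforehand. The random block took arrays of 1 genotype and number as 1 animal across tissues. The cause of each change below was not tested, except that a fit of fewer arrays has fewer degrees of freedom.

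In dko extraocular muscle 2 probe sets passed. The count was 0 with scaling to a common 75th percentile, 1 with the raised offset, 0 with only the arrays compared, 14 with the replicate block within tissue, 0 with the random block, 12 with the common block and 0 with numbers 1 and 2 only. Leaving out 1 array gave 0 to 0. With the block, the 14 became 0 with the lowered offset, 8 without a filter and 0 with only the arrays compared. Without 1 array it was 0 to 4. The 11 lists became 7 with numbers 1 and 2 only, 3 with an estimated correlation and 0 with block and estimated correlation together. Without 1 array they were 8 to 12.

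In dko leg 5 probe sets passed. The count was 1 with the lowered offset, 15 with the raised offset, 9 with the filter at the 60th percentile, 0 with only the arrays compared, 107 with the block within tissue, 1 with the random block, 144 with the common block and 0 with numbers 1 and 2 only. Leaving out 1 array gave 1 to 17. With the block, the 107 became 49 with the lowered offset, 314 with the raised offset, 270 with the filter at the 60th percentile, 298 with trend and robust and 1 with only the arrays compared. The range without 1 array was 8 to 60. The 13 lists became 8 with the filter at the 60th percentile, 7 with an estimated correlation and 1 with block and estimated correlation together. With 1 array left out they were 11 to 16.

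In dko heart 0 probe sets passed in every setting without the block, except that leaving out 1 array gave 0 to 1. The blocked count was 1 with the raised offset, 1 with the filter at the 60th percentile and 1 with trend and robust. Leaving out arrays singly gave 0 to 1. The 4 lists became 0 with an estimated correlation and 0 with it and the block. With 1 array left out they were 3 to 8. The overlap between tissues, 0, became 4 with the block within tissue and 2 with the common block.

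For the difference between extraocular muscle and leg, 0 became 1 with the raised offset, 3 with the block within tissue, 6 with the random block and 5 with the common block. Without 1 array it was 0 to 2. With the block, 3 became 1 with the lowered offset, 6 with the raised offset, 1 without a filter, 5 with the filter at the 60th percentile, 8 with trend and robust and 1 with only the arrays compared. The range without 1 array was 0 to 2. For heart against leg, 0 became 1 with the raised offset, 6 with the block within tissue, 4 with the random block and 4 with the common block. Leaving out arrays singly gave 0 to 1. With the block, 6 became 2 with the lowered offset, 32 with the raised offset, 35 with trend and robust and 3 with only the arrays compared. Without 1 array it was 2 to 8. For extraocular muscle against heart the count was 0 in every setting, except 0 to 1 with the block when 1 array was left out. Lists went from 6 to 0, from 13 to 8 and from 8 to 0 with an estimated correlation, and the last also to 4 with numbers 1 and 2 only. With block and estimated correlation together they were 1, 0 and 0. Leaving out 1 array gave 3 to 10, 9 to 17 and 4 to 15.

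For mdx extraocular muscle against leg, 357 became 66 with only the arrays compared, 1217 with the block within tissue, 1029 with the random block and 1106 with the common block. The range without 1 array was 178 to 270. The 10 lists became 2 with an estimated correlation and 0 with it and the block. With 1 array left out they were 7 to 15. For mdx heart against leg, 886 became 502 with only the arrays compared, 2164 with the block within tissue, 1951 with the random block and 2026 with the common block. Leaving out arrays singly gave 630 to 809. The 14 lists became 4 with an estimated correlation and 4 with it and the block. With 1 array left out they were 11 to 14.

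Some results changed direction. With numbers 1 and 2 only, Utrn 92508_s_at in leg had a log2 difference of 0.0107, Dmd in heart -0.129 and the oxidative phosphorylation list in leg a median of 0.0361. Leaving out 1 array gave -0.0839 to 0.21 for Dmd in heart, negative without dko array 1 (-0.0367), mdx array 3 (-0.0152) or dko array 3 (-0.0839). For Dmd in leg it gave -0.547 to 0.0914, positive without dko array 3. For the oxidative phosphorylation list in leg it gave -0.273 to 0.0866, positive without mdx array 3. In extraocular muscle the median of the regeneration and embryonic muscle list went from 0.0372 to -0.00248 without mdx array 1, and that of the cardiac stress response list from 0.0955 to -0.0599 without mdx array 1 and to -0.0954 without dko array 3. For extraocular muscle against heart the median of the skin and mucosal epithelium list went from -0.169 to 0.00986 without extraocular dko array 3, although its call was kept. Rescaling or quantile normalization shifted the median log2 difference of all probe sets by -0.015 to 0.014. The slow contractile list in leg kept direction and call in every setting run. The macrophage lists in extraocular muscle and leg, and the extracellular matrix, regeneration, chemokine and cardiac stress lists in leg, kept theirs in every setting but 1, losing the call with block and estimated correlation together. Among the called single genes 1648 values kept their side of the threshold and 162 did not in settings other than leaving out 1 array, and 687 and 225 when 1 array was left out. For genes called with the block the counts were 258 and 89, but 74 and 190 when 1 array was left out. For lists they were 910 and 194, and 519 and 116. The signal over background limits what can be said of dim genes. The Utrn group means of 258.1 to 748.1 lie near the offset of 166.7, so the fold change of Utrn depends on the offset.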

Other observations

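The test of a signal ceiling below was chosen only after the result was seen, as were the splits with the replicate block. The other splits were set out beforehand.

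Further genes rose in dko leg muscle with the replicate block. They were Sox11, a developmental transcription factor (log2 difference 1.26, adjusted p = 0.0151), C1qtnf3, a secreted relative of complement C1q (1.54, adjusted p = 0.0289), Runx1, a transcription factor known to be raised in denervated muscle (1.00, adjusted p = 0.0292), and Myf5, a regulator of muscle precursor cells (0.93, adjusted p = 0.0456). None of these passed without the block (adjusted p = 0.242, 0.0856, 0.809 and 0.522 for Sox11, C1qtnf3, Runx1 and Myf5).

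Some further genes differed between the mdx controls. Cdo1, which breaks down cysteine, read 3528 ± 469 in mdx extraocular muscle and 217.2 ± 63.1 in mdx leg (9.65-fold higher, adjusted p = 2.66e-05), and the desaturase Scd1 16330 ± 7780 and 1271 ± 489 (10.8-fold higher, adjusted p = 0.00669). Lower were the collagenase Mmp13 (152.3 ± 106 and 1561 ± 777, 5.27-fold lower, adjusted p = 0.000832) and Lgals3 (876.1 ± 510 and 4655 ± 2280, 4.77-fold lower, adjusted p = 0.00856). Alas2, the haem-synthesis enzyme of erythroid cells, read 12770 ± 2980 in mdx heart and 535.6 ± 115 in mdx leg (18.3-fold higher, adjusted p = 6.93e-07). The desmosome gene Dsp read 23700 ± 4850 and 317.3 ± 87.8 (49.2-fold higher, adjusted p = 6.3e-09).

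Actin and glycolytic genes read unevenly among the mdx leg arrays. Acta1 read 256.1, 247.7 and 6656.3 on arrays 1, 2 and 3, and Aldoa, a glycolytic enzyme abundant in muscle, 344.5, 14.7 and 28445.8. Of the 125 brightest probe sets of mdx leg array 3, 14 were at least 8-fold lower on array 1 or 2. Among the 12 of these with a symbol, 9 were fast-fibre or glycolytic genes, Actn3, Casq1, Atp2a1, Tnnc2, Myl1, Pkm, Ldha, Eno3 and Myh4. In the opposite direction there were 0, and in the other groups there were 1 to 6. This is consistent with a ceiling on bright signals on the arrays numbered 1 and 2, where saturated probes may be scored as low. Probe-level values, which would settle it, were not available. The log2 difference of Acta1 in leg on the arrays numbered 3 was 1.61, from 1 array of each genotype. This argues against arrays 1 and 2 as its only source, but whether that pair was free of the same effect is not known. Tests of the fast contractile and glycolysis lists that use the mdx leg arrays rest in part on these uneven readings.

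Other splits of the arrays were counted for each comparison. With 3 arrays against 3 there are 10 splits, and with pairs kept parted there are 4, too few for a share under 0.05. In extraocular muscle 1 of 10 splits called as many probe sets as the real one (2, highest other 1) and 1 as many lists (11, highest other 8). With the block 1 of 4 did (14, highest other 0). In leg 1 of 10 called as many probe sets (5, highest other 4) and 1 as many lists (13, highest other 11). With the block 1 of 4 did (107, highest other 0). In heart 10 of 10 called at least 0 probe sets (highest other 3) and 6 at least 4 lists (highest other 9). With the block 4 of 4 called at least 0 (highest other 0). The heart splits with more lists than the real one point to a structure of the samples that is not genotype. For mdx extraocular muscle against leg 1 of 10 called as many probe sets (357, highest other 0) and 2 as many lists (10, highest other 12). With the block 1 of 4 did (1106, highest other 1). For mdx heart against leg 1 of 10 called as many probe sets (886, highest other 1) and 1 as many lists (14, highest other 10). With the block 1 of 4 did (2026, highest other 1).

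The overlap of extraocular muscle and leg was also counted over 100 splits. Without the block all 100 shared at least 0 probe sets (highest other 0), which says nothing of chance since every split reaches 0. With the block 2 of 100 shared at least the 4 of the real split (highest other 4). Both had the real parting of the extraocular and leg arrays, as had all 8 splits that called any probe set in both tissues. The splits therefore repeat the counts of each tissue and do not test the overlap, and whether chance gives the sharing of Kcne1l, Ms4a6c, Myl4 and S100a4 was left open.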
